A study of Mus musculus with 2 samples.

How the data were processed

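H3K4me1 was measured by ChIP-seq in 2 biological replicates of mouse limb at embryonic day 11.5, each with 2 technical replicates and a library size range of 300 to 500 bp per the labels. The replicates were pools of limbs from 109 and 88 embryos of both sexes. The authors deposited 4 peak lists on mm10, namely 1 per replicate, 1 from the reads of both together (pooled), and 1 of pooled peaks kept as replicated. Each list was made against the same 2 control files. The aligner, the peak caller and their versions are not given in the sources used here, nor is the rule by which the replicated list was made. The fold enrichment of ChIP over control at each peak, a ratio, is as deposited by the authors. The significance of each peak was deposited as -log10 p, with no p-value on its plain scale. A further deposited column gives the -log10 q, an adjusted p-value on the same scale. The last deposited column is the distance in bp of the summit from the start of the peak, counted from 0. These contents were checked on the files. Read counts and the control itself were not analysed here, so the depth per sample is unknown.

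Peak lists were used as deposited, with no filter. All peaks lay on chromosomes 1 to 19 and X, none ended past its chromosome and no summit lay in an assembly gap. Genes were those of GENCODE vM21 on GRCm38, the assembly of mm10, with 55450 genes, of which 21938 were protein-coding on chromosomes 1 to 19, X and Y. Positions are given counted from 1. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlaps of the replicates were also counted with bedtools 2.31.1, which gave the same 63380 and 58483 peaks.

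The replicated list was the main list. The lists of replicate 1 and replicate 2 gave the spread, as the mean and SD over 2 replicates or as separate values. As the series holds 1 group, no test between groups was made, and tests permute genes or places, so they describe these peak lists. Before the data were examined, the gene lists, motifs, comparisons, most alternatives and the rule for named genes were fixed.

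Summits were put in promoters (within 1 kb of any annotated TSS), exons, introns or intergenic DNA, in that order. They were compared with 100 random placements of single positions, 1 per summit, on the same chromosomes outside gaps (seed 11). Peak widths played no part in these placements. Coverage around TSS was read every 100 bp to 10 kb on either side. TSS were called CpG-rich when the ratio of observed to expected CpG within 500 bp was at least 0.6. For each protein-coding gene the length covered by peaks within 50 kb of the TSS was summed. The median of each of 22 lists, 21 written by hand and 1 of all olfactory receptor genes, was compared with 10000 random lists of the same size and the same deciles of gene length. This gave a two-sided permutation p, whose smallest value is 0.0002, adjusted by Benjamini-Hochberg over the 22 lists. All listed genes were found in the annotation. Members in the top 10% by covered length in the replicated list and both replicates, and members within 50 kb of the 500 longest clusters of peaks joined across gaps under 12.5 kb, were counted against all other protein-coding genes by Fisher's exact test, two-sided, adjusted over lists. Hox clusters ran from the first to the last gene, with flanks of 500 kb. GC content and CpG within 250 bp of summits were compared with 5 random placements. Motifs were counted there against flanks 10 kb away that no peak covers, with up to 20 permutations of the letters of each motif. Motifs with fewer than 50 matches in the flanks were left out.

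The text names, per gene list, the 3 members with the longest covered length in the replicated list and 1 with the shortest. It also names the 15 longest clusters by the TSS they hold or the nearest TSS, the 10 highest peaks and a set of limb loci chosen in advance. Other genes named were chosen after their values were seen. Shares of peaks carry Wilson 95% intervals where given.

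For each peak of a list, a Poisson model was solved for the pileup and the background that give the deposited fold and -log10 p together. Peaks of the replicates were to be met to within 0.001 in -log10 p. A looser limit held for the pooled list, and the step of its reads was itself found from the same values. All peaks of the replicate and pooled lists were met, in replicate 1 with the chance of at least as many reads, in replicate 2 with the chance of more reads, and in the pooled list with reads in steps of 0.509. The relative depth follows from the scaling of the control in each replicate. It rests on the assumption that the caller used such a model.

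The methods were tested on simulated data. Of 100 lists of 20 genes with no difference, 5% fell under a permutation p of 0.05, and of 100 lists raised 3-fold plus 1 kb, 84% did. For these lists the covered lengths were first shuffled among genes of the same length decile. The rates therefore do not cover lists of neighbouring genes, whose windows overlap. Random places gave a promoter ratio of 0.971, and planted places gave 3.20 against a planted 3.20. The height model recovered 100% of pileups to within 0.01, in whole reads and in fractions of a read. A planted motif stood above all 20 permutations, and 1 of 17 motifs that had not been planted did so too.

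Alternatives were each replicate alone, the pooled list, only peaks of -log10 q of at least 3, and the stronger part of the list by p. Others were promoters of 2.5 kb, peak midpoints, protein-coding genes only, windows of 20 and 200 kb, random lists matched by TSS density or not at all, members at least 100 kb apart, the number or highest fold of peaks, a top 5%, a gap of 3 kb, the 1000 longest clusters, summits within 100 bp, and stricter overlaps. For chromosome coverage, sequence and the TSS profile, the replicate lists and, for the first and second of these, the pooled list were added after seeing the data. So were Fisher's exact tests with members at least 100 kb from each other and other genes at least 100 kb from each other.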

Results

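H3K4me1, the monomethylated form of histone H3 lysine 4 that marks enhancers and the flanks of active promoters, was measured by ChIP-seq in mouse limbs at embryonic day 11.5. The samples formed 1 group of 2 biological replicates, pools of limbs from 109 and 88 embryos of strain B6NCrl of both sexes. The deposited peak list of replicate 1 held 82506 peaks covering 30.1 Mb of the mm10 genome, and that of replicate 2 held 149679 peaks covering 60.7 Mb. The mean was 116092 ± 47498.5 peaks (SD, n = 2). Reads of both replicates together gave a pooled list of 94426 peaks, of which the authors kept 73279 as replicated, covering 35.1 Mb or 1.32% of the genome outside gaps. Values below are from this replicated list unless a replicate is named. The files give no read totals, so the sequencing depth is unknown. Under a Poisson model of the deposited fold enrichment and p, the median peak stood on 14 reads in replicate 1 (exact Poisson 95% interval 7.65 to 23.5) and on 13 in replicate 2 (6.92 to 22.2). Such intervals cover counting error only. With a single tissue, age and mark there was no contrast between groups, and the comparisons are between places in the genome, with the replicates giving the spread.

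The first comparison asked where in the genome the mark lay. Promoters held 20.8% of the peak summits, against 6.41% of random placements, a log2 ratio of 1.7 ± 0.02 (SD over 100 placements). Introns held 48.5% of summits against 40.6% at random (log2 ratio 0.26 ± 0.01), and exons held 4.39% against 3.43% (0.35 ± 0.03). Intergenic DNA held 26.3% against 49.6% at random, a log2 ratio of -0.91 ± 0.01. For each of the 4 locations, 0 of 100 random placements lay as far from the random mean. Most summits nevertheless lay far from the transcription start sites (TSS) of protein-coding genes. Of all summits, 68.7% lay more than 10 kb from the nearest of these, against 85.1% of random places. A single TSS was taken per gene here, whereas promoters lay around any annotated TSS, so a promoter summit can count among the 68.7%. The median distance was 33539 bp against 69030 bp at random. Peak height did not separate the locations, with a median fold enrichment of 3.4 at promoters, 3.41 in exons and 3.39 in both introns and intergenic DNA. The log2 ratios at promoters were 1.65 in replicate 1 and 1.5 in replicate 2, and those of intergenic DNA were -0.90 and -0.81. With promoters taken as 2.5 kb rather than 1 kb on either side of a TSS, the excess in exons was gone (log2 ratio -0.0076, with 40 of 100 placements as far).

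**Figure D1:**
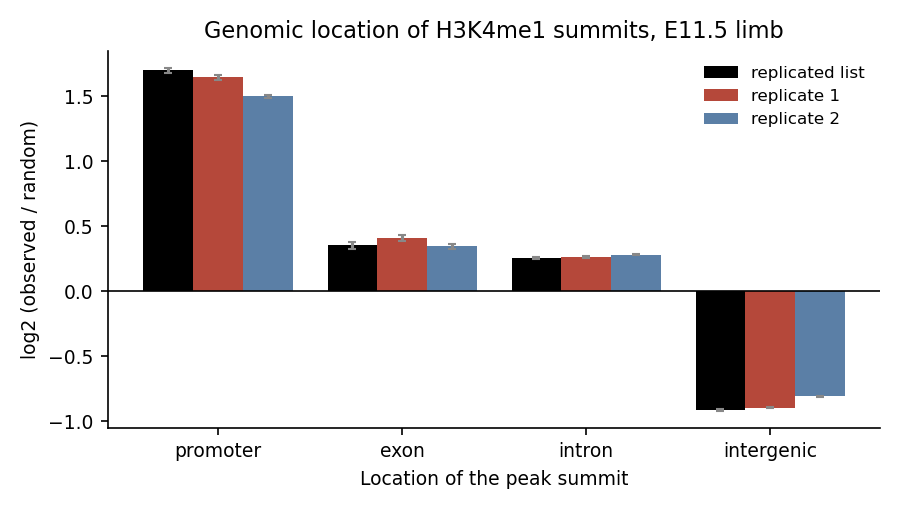
Log2 ratio of the share of peak summits in promoters, exons, introns and intergenic DNA to that of random placements, for the replicated list and each replicate, with bars of 1 SD over 100 placements. In the replicated list promoters stand at 1.7 and intergenic DNA at -0.91, and the replicates share the direction of all 4 locations.

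Taken over the 21938 protein-coding TSS together, the mark formed a pair of shoulders with a dip at the start site itself. Peaks covered 4.95% of TSS at the start site, 6.71% at 600 bp upstream and 13.8% at 1000 bp downstream, falling to 1.80% at 10 kb upstream and 2.25% at 10 kb downstream. The shoulders were tall at CpG-rich promoters, the class typical of broadly expressed and developmental genes. At these 10083 TSS peaks covered 3.46% of start sites but 10.7% of positions 1000 bp upstream and 23.6% of positions 1000 bp downstream. At the 11855 CpG-poor TSS, 6.21% of start sites were covered and the downstream maximum, at 600 bp, was 6.58%. The upstream maximum there, 5.90%, was under the share at the start site, as in each replicate, so these TSS had no upstream shoulder. Replicate 2, with the longer list, gave higher shares, also with a dip at the start site. Over all TSS it had 7.95% at the start site, 11.7% upstream and 20.3% downstream, against 4.56%, 5.78% and 11.04% in replicate 1. At CpG-rich TSS the upstream maximum was 8.89% in replicate 1 and 18.6% in replicate 2, and the downstream maximum 18.5% and 34.2%. The division by CpG content was chosen after the data were seen, and no test was made between the classes.

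**Figure D2:**
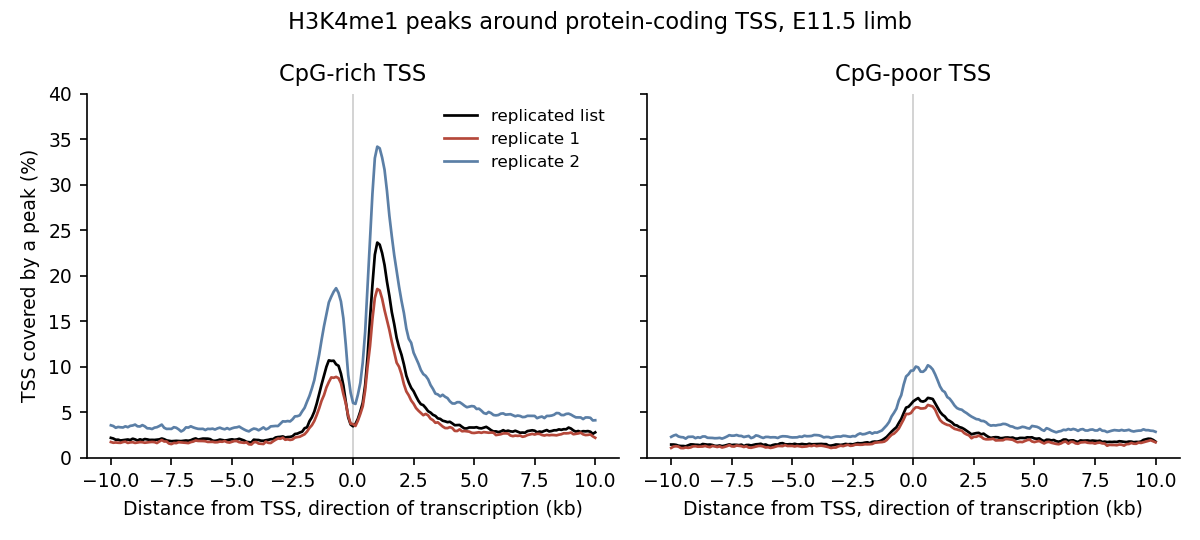
Percent of protein-coding TSS covered by an H3K4me1 peak at each distance from the TSS, in kb along the direction of transcription, for CpG-rich and CpG-poor TSS, in the replicated list and each replicate. CpG-rich TSS dip to 3.46% at the start site and reach 23.6% at 1 kb downstream in the replicated list, while CpG-poor TSS stay at or under 6.58%.

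The next comparison asked whether genes of limb development carried more H3K4me1 than other genes, counting for each gene the length covered by peaks within 50 kb of its TSS. Of 10 limb lists fixed before the data were examined, 8 stood above random lists matched for gene length. The transcription factors of the limb mesenchyme had a median of 7.27 kb (27 genes) against 0.9 kb at random. The signalling lists had medians of 8.68 kb for WNT (16 genes), 7.32 kb for retinoic acid (13 genes), 7.19 kb for SHH and GLI (14 genes), 5.84 kb for FGF (17 genes) and 3.38 kb for BMP (15 genes), against random medians of 0.740 to 0.9 kb. HoxA and HoxD genes had the longest coverage, a median of 28.1 kb over 20 genes, and chondrogenic genes had 3.50 kb over 20 genes. The permutation p was 0.0002, the smallest that 10000 random lists can give, for the mesenchyme, Hox, SHH, FGF, WNT and retinoic acid lists (adjusted p = 0.000629 over 22 lists). Chondrogenic genes had an adjusted p of 0.00440 and BMP signalling 0.0244. All 8 lists were also above random in each replicate alone, at adjusted p values of 0.0186 or lower. The calls of BMP and of chondrogenic genes were lost with only peaks of -log10 q of at least 3 (permutation test, adjusted p = 0.0666 and 0.0675), and those of BMP and of retinoic acid with a window of 200 kb (0.301 and 0.117). BMP also lost its call among the stronger peaks by p (0.0620) and with the number of peaks in place of covered length (0.314), and chondrogenic genes lost theirs with the highest fold in the window (0.265).

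Among the mesenchymal transcription factors, Prrx2, a homeobox gene of limb mesenchyme, had 32.4 kb covered (33.2 ± 5.36 kb over the replicates, SD, n = 2). Lmx1b, which sets dorsal identity, had 26.0 kb (30.3 ± 9.72 kb), and Tbx4, the T-box factor of the hindlimb, had 20.4 kb (23.3 ± 7.15 kb). The shortest of the list was Osr1, a zinc finger factor, with 1.77 kb. In SHH signalling, the receptor gene Ptch1 had 20.1 kb, the co-receptor genes Boc and Cdon had 15.1 and 9.58 kb, and the BMP antagonist gene Grem1 had 0.746 kb. In FGF signalling, the receptor gene Fgfr1 had 16.2 kb, the feedback inhibitor gene Spry4 had 12.2 kb and the ligand gene Fgf17 had 11.4 kb. Fgf10, the mesenchymal ligand needed for limb outgrowth, had 0.374 kb, with no peak in the window in replicate 1 and 2.34 kb in replicate 2. In BMP signalling, the inhibitory SMAD genes Smad7 and Smad6 had 31.5 and 26.8 kb, the ligand gene Bmp7 had 19.9 kb, and the receptor gene Bmpr2 had 0.678 kb. In WNT signalling, Axin2, a target and inhibitor of the pathway, had 19.7 kb, the receptor gene Ror2 had 18.7 kb and the ligand gene Wnt11 had 18.0 kb, while the antagonist gene Dkk1 had no replicated peak in its window. In retinoic acid signalling, the receptor genes Rara and Rarg had 34.8 and 14.3 kb, Crabp2, a retinoic acid binding protein, had 19.3 kb, and Rdh10, an enzyme of retinoic acid synthesis, had 0.361 kb. Of the chondrogenic genes, the transcription factor gene Runx3 had 15.1 kb, the cartilage matrix genes Comp and Col2a1 had 13.5 and 12.1 kb, and the collagen gene Col11a1 had none. In replicate 2 the median over all protein-coding genes was 1.997 kb, against 0.876 kb in the replicated list and 0.774 kb in replicate 1, and single genes were longer there by over 1.5 times in cases such as Cdon (15.7 kb) and Osr1 (4.91 kb).

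Limb ectoderm and limb muscle did not pass the test. Ectoderm and epidermis genes had a median of 1.77 kb (20 genes, permutation test, adjusted p = 0.344), from 12.2 kb at the epidermal regulator Grhl3, 10.2 kb at Sp6, a factor of the apical ectodermal ridge, and 8.50 kb at the homeobox gene Dlx2 down to none at the keratin gene Krt14. Muscle genes had a median of 1.97 kb (19 genes, permutation test, adjusted p = 0.237), from 31.9 kb at the fast troponin gene Tnnt3, 15.2 kb at the myoblast fusion gene Mymk and 11.2 kb at the acetylcholine receptor gene Chrna1 down to none at Mef2c, a muscle transcription factor. Both lists passed with a window of 20 kb (permutation test, adjusted p = 0.0444 and 0.0189), and muscle genes passed when matched on the density of TSS (0.0370).

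None of the 4 lists for other cell types that a limb could hold passed the test. Endothelial genes had a median of 1.81 kb (16 genes, permutation test, adjusted p = 0.264), macrophage genes 2.5 kb (15 genes, 0.122), erythroid genes 0.231 kb (15 genes, 0.264) and Schwann cell and melanocyte genes 0.382 kb (14 genes, 0.344). Members nevertheless varied widely. Fli1, an ETS factor of endothelium, had 27.1 kb, the endothelial surface genes Eng and Plvap had 14.4 and 8.53 kb, and 3 endothelial genes, Cdh5, Emcn and Tek, had none. The erythroid factors Nfe2 and Klf1 had 18.6 and 6.61 kb and the anion exchanger gene Slc4a1 had 4.51 kb, whereas 7 of the 15 erythroid genes, the embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y among them, had none. The macrophage genes Cd68, Csf1r and Fcgr1 had 6.19, 4.40 and 3.90 kb and 5 others, Ptprc among them, had none. Sox10, a neural crest factor, had 3.21 kb, the melanosome gene Pmel had 2.81 kb and the myelin gene Mpz had 2.63 kb, and 6 genes of that list, the pigment gene Tyrp1 among them, had none.

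Of 7 lists for other organs, 6 did not pass the test and 1, the olfactory receptors, fell below random. Of the 1134 olfactory receptor genes, which are expressed in the nose, 1055 had no peak within 50 kb, giving a median of 0 kb against 0.890 kb at random (adjusted p = 0.000629, and the smallest that the permutation can give before adjustment, 0.0002). The longest coverage of that list was 3.33 kb at Olfr221 and 2.45 kb at the neighbours Olfr155 and Olfr157. This call was lost with only peaks of -log10 q of at least 3, where the random median was also 0 (permutation test, adjusted p = 1). Medians of the other lists were 0.799 kb for hepatocytes (20 genes, permutation test, adjusted p = 0.771), 1.36 kb for pancreas and intestine (17 genes, 0.495), 1.39 kb for neurons (20 genes, 0.412), 1.84 kb for lymphocytes (15 genes, 0.412), 2.03 kb for germ cells (15 genes, 0.275) and 2.05 kb for cardiomyocytes (17 genes, 0.237). The longest coverage was 6.16 kb at Apoa2, 4.27 kb at Foxa3 and 2.26 kb at Hnf1a for hepatocytes, and 24.4 kb at Cpa1, 12.3 kb at Cdx1 and 6.83 kb at Lgals4 for pancreas and intestine. Camk2a, Slc17a7 and Neurod2 led the neuronal list with 10.9, 7.04 and 6.02 kb, and Cd4, Cd79b and Lck led the lymphocyte list with 12.35, 7.81 and 7.10 kb. Germ cell genes were led by Prm1, Prm2 and Mael with 6.91, 5.19 and 3.24 kb, and cardiomyocyte genes by Myl3, Hand1 and Myl7 with 10.7, 6.58 and 3.95 kb. Each of these 6 lists held members with no peak, among them Tdo2, Ins2, Syt1, Ms4a1, Sycp1 and Actn2. Housekeeping genes had a median of 3.01 kb (18 genes, permutation test, adjusted p = 0.0893), with 16.7 kb at the ribosomal gene Rplp0, 10.5 kb at Polr2a, 8.23 kb at Rps18 and none at Pgk1. They passed with a window of 20 kb (permutation test, adjusted p = 0.000733), with the stronger peaks by p (0.0210) and without matching for gene length (0.0361).

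**Figure D3:**
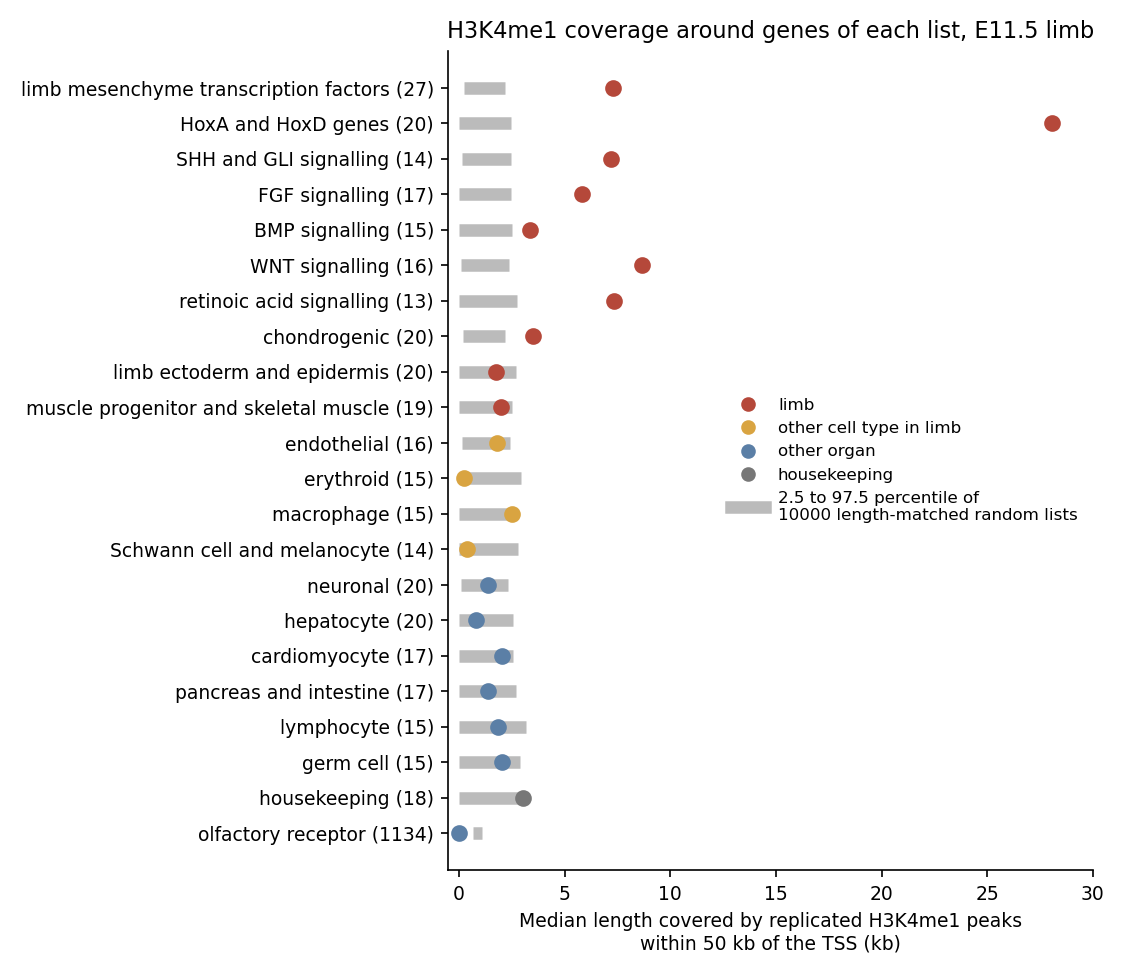
Median length in kb covered by replicated H3K4me1 peaks within 50 kb of the TSS for each of 22 gene lists (points, coloured by class, with the number of genes in brackets), over the central 95% of 10000 random lists matched for gene length (grey bars). HoxA and HoxD genes stand at 28.1 kb, mesenchymal transcription factors at 7.27 kb, and olfactory receptors at 0 kb.

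Genes with the very longest coverage were also more frequent in 7 of the limb lists than among other genes. Of all protein-coding genes, 1871 (8.53%) lay in the top 10% by covered length in the replicated list and in both replicates, at 6.66 kb or more in the replicated list. All 20 HoxA and HoxD genes did, as did 14 of 27 mesenchymal transcription factors, 8 of 16 WNT, 7 of 13 retinoic acid, 8 of 17 FGF, 6 of 14 SHH and 6 of 15 BMP genes. These 7 passed Fisher's exact test, with adjusted p values from 4.15e-21 for the Hox genes to 0.00267 for BMP. Chondrogenic genes did not (4 of 20, Fisher's exact test, adjusted p = 0.156), and 0 of 1134 olfactory receptor genes were in the top 10% (adjusted p = 2.81e-44). With the top 5% in place of the top 10%, the SHH and FGF lists no longer passed. Neighbours are not independent, so members were also kept at least 100 kb from each other, and other genes likewise among themselves. A member and another gene could still lie closer. In this setting, chosen after the data were seen, the same 7 lists passed (3 of 3 Hox genes, Fisher's exact test, adjusted p = 0.000803) and so did endothelial genes (4 of 16, adjusted p = 0.0448). The 3 Hox genes came from HoxA and HoxD only, so some still shared a cluster and were not independent.

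The covered length near a gene can belong to a neighbour. Of the 80 limb genes in the top 10%, the median share of covered length that lay closer to the gene's own TSS than to any other protein-coding TSS was 82.7%, while their own territory took a median of 60.8% of the window. The share was 27.6% for 5 such genes of other cell types (41.2% of the window), 21.7% for 8 genes of other organs (24.8%) and 21.7% for 4 housekeeping genes (25.8%). Shares above 50% were those of the endothelial genes Fli1 (99.2%, with 96.7% of the window as its own territory) and Erg (100% of both), the neuronal gene Camk2a (78.2%, with 51.2% of the window), the B cell gene Cd79b (55.2%, with 25.7% of the window) and the heart muscle gene Myl3 (50.2%, with 45.3% of the window). Shares under 10% were those of Nfe2 (7.53%), Plvap (6.62%), Cdx1 (7.10%), Slc17a7 (3.51%) and Rps18 (8.11%), with 0% at Cd4 and Lgals4. The lengths given above for these genes thus lay mostly nearer to the TSS of other genes. These shares, and the genes named here, were chosen after the data were seen, and no test was made between classes.

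The Hox clusters, whose genes pattern the limb along its axes, were asked about one by one. HoxA (chromosome 6, 52155590 to 52260880) was covered by peaks over 38.9% of its length (38.4 ± 8.27% over the replicates, SD, n = 2). HoxD (chromosome 2, 74668310 to 74765142) was covered over 30.1% (31.8 ± 9.11%), HoxC (chromosome 15, 102921103 to 103036852) over 27.9% (29.8 ± 6.37%) and HoxB (chromosome 11, 96194316 to 96368256) over 12.4% (14.1 ± 7.77%). Within HoxA the mark lay mostly over the anterior genes. From Hoxa1 to Hoxa7 peaks covered 55.8% of 66.3 kb (44.9% in replicate 1, 62.5% in replicate 2), and from Hoxa9 to Hoxa13 they covered 10.6% of 37.8 kb (12.0% and 12.9%). In HoxD the same division gave 33.6% from Hoxd1 to Hoxd8 (26.9% and 41.0%) and 21.5% from Hoxd9 to Hoxd13 (20.6% and 32.2%). The windows of Hoxa5, Hoxa6 and Hoxa3 held 40.6, 40.4 and 38.4 kb of peaks, and Hoxd13 had the shortest coverage of the list, 13.8 kb. The widest peak of HoxA, 2789 bp from 52183125 to 52185913, was also its highest, with a fold enrichment of 6.51. Outside the clusters, the 500 kb beyond Hoxc4 held 53.7 kb of peaks (45.7 kb in replicate 1, 72.9 kb in replicate 2), and the other 7 flanks held 12.9 to 21.9 kb. The division into anterior and posterior genes was made after the data were seen, no test was made between clusters, and the windows of neighbouring Hox genes overlap. With only genes at least 100 kb apart, 3 Hox genes were left, with a median of 14.4 kb (permutation test, adjusted p = 0.00935). As they came from HoxA and HoxD only, some still shared a cluster and were not independent.

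**Figure D4:**
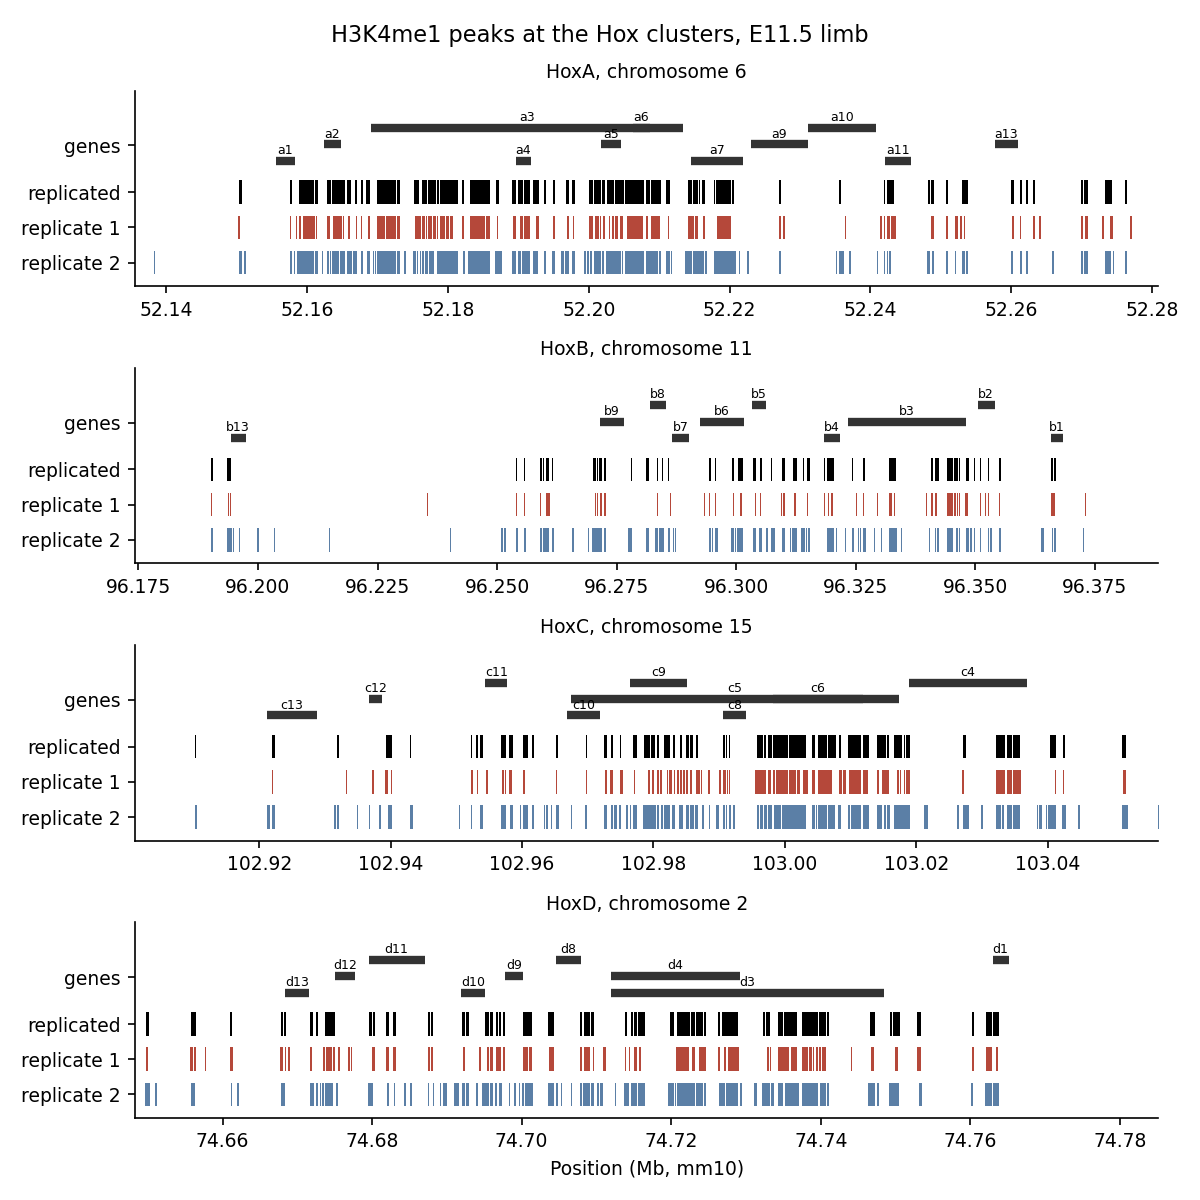
Maps of the HoxA, HoxB, HoxC and HoxD clusters on mm10 (position in Mb), with genes as dark bars and peaks as blocks for the replicated list and each replicate. Peaks cover 55.8% of HoxA from Hoxa1 to Hoxa7 and 10.6% from Hoxa9 to Hoxa13.

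Joining neighbouring peaks across short gaps gave 22318 clusters, of which the 500 longest by covered length held 26.6% of all peak sequence. The longest lay on chromosome 8 from 120250789 to 120602926, over Gse1 and the TSS of Gins2, a replication gene, and held 169.8 kb of peaks (150.9 kb in replicate 1, 193.3 kb in replicate 2). The second, with 77.7 kb, lay on chromosome 11 from 117231669 to 117498920 over Sept9, a septin gene, and the TSS of Gm11733. The third covered Ror2 on chromosome 13 (53110160 to 53318350, 65.5 kb), and the fourth Tanc1 on chromosome 2 (63.3 kb). The fifth held the TSS of Lsp1, Mrpl23 and Tnnt3 (59.1 kb). The next lay 2.44 kb from the TSS of Tead1, a transcription factor of the Hippo pathway (57.9 kb), and the one after it lay within Prdm16, a transcription factor gene, 35.5 kb from its TSS (57.4 kb). The eighth held the TSS of 1700001O22Rik, Cstad and Ntmt1 (55.5 kb), the ninth those of Ahdc1 and Wasf2 (51.0 kb), and the next lay nearest to the forkhead gene Foxl1 (50.7 kb). The last 5 of the 15 longest, with 49.8 to 47.8 kb, lay nearest to the zinc finger gene Casz1 or held the TSS of Faap20, Morn1, Rer1 and the SMAD inhibitor gene Ski, of Nfix and 9 neighbours, of Ssbp3, and of Cox8a, Flrt1, Macrod1 and Otub1. Genes within 50 kb of the 500 longest clusters made up 5.33% of protein-coding genes. They included all 20 HoxA and HoxD genes (Fisher's exact test, adjusted p = 3.21e-25), 8 of 27 mesenchymal transcription factors (0.00025), 6 of 14 SHH genes (0.00025), 6 of 13 retinoic acid genes (0.000206), 5 of 15 BMP genes (0.00299), 5 of 16 WNT genes (0.00357) and 4 of 17 FGF genes (0.0301). The FGF call was lost without replicate 2, with a gap of 3 kb and with only peaks of -log10 q of at least 3, and the last setting also ended the call of the mesenchymal factors. With members, and separately other genes, at least 100 kb apart the same 7 lists passed, with 3 of 3 Hox genes (Fisher's exact test, adjusted p = 0.000469). Some of these Hox genes still shared a cluster.

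The highest single peak lay in intron 4 of Ssbp3, a cofactor of LIM homeodomain proteins, on chromosome 4 from 106976238 to 106978451, with a fold enrichment of 11.2 (11 in replicate 1, 11.2 in replicate 2). The next, at a fold of 8.91 each, lay 26.5 kb from the TSS of Snai1, a factor of mesenchymal cells (chromosome 2, 167564146 to 167565532), in intron 2 of Ahdc1 (chromosome 4, 133041087 to 133048753) and in intron 1 of Gm20388, 67.1 kb from the TSS of Gse1 (chromosome 8, 120291796 to 120297402). The others of the 10 highest had folds of 8.77 to 8.35. They lay in intron 3 of Zmiz1, intron 1 of the sulfotransferase gene Chst11, 41.1 kb from Actrt2, in intron 1 of Rara, intron 7 of the cytokine receptor gene Cntfr, and intron 1 of the focal adhesion gene Pxn. The Chst11 peak differed most between the replicates, with folds of 5.35 and 11.75. These heights are the authors' own values, taken at the summit.

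Genes central to limb patterning differed widely in their coverage, given here as kb of peaks within 50 kb of the TSS. Tbx4 (ENSMUSG00000000094.12, chromosome 11, 85886422 to 85916097) had 20.4 kb, more than 99.4% of genes. Tbx5, its forelimb counterpart (ENSMUSG00000018263.11, chromosome 5, 119832668 to 119885219), had 4.10 kb (81.6%; 3.44 kb in replicate 1, 10.5 kb in replicate 2). Pitx1, a hindlimb homeobox gene, had 7.48 kb (9.14 ± 3.99 kb over the replicates, SD, n = 2). Shh, the signal of the posterior limb margin (ENSMUSG00000002633.4, chromosome 5, 28456815 to 28467256), had 2.22 kb (2.64 ± 1.40 kb). Gli3, a transcription factor of SHH signalling, had 7.19 kb in its window (5.06 kb in replicate 1, 12.96 kb in replicate 2) and 41 peaks covering 18.8 kb within the gene. Ptch1 carried its highest peak in intron 15, at a fold of 6.93. Among the outgrowth and skeletal genes, Prrx1, a mesenchymal homeobox gene, had 9.56 kb (10.8 ± 7.18 kb) and Hand2, a factor of the posterior limb, had 8.55 kb (11.3 ± 5.32 kb). Sox9, the chondrogenic regulator, had 6.22 kb (7.6 ± 3.03 kb), Fgf8, the ridge signal, had 4.62 kb (5.59 ± 2.18 kb) and Bmp2 had 1.33 kb (2.24 ± 1.46 kb). In replicate 2 alone, the longer list, these were all over 1.5 times as long, with 15.9 kb at Prrx1, 15.03 kb at Hand2, 9.74 kb at Sox9, 7.13 kb at Fgf8 and 3.27 kb at Bmp2. Fgf10 had 6 peaks covering 2.13 kb within the gene, most of which lies outside its window, with 5 peaks in replicate 1 and 15 in replicate 2. Col2a1, the main cartilage collagen gene (chromosome 15, 97975602 to 98004695), had 12.1 kb, with its highest peak, at a fold of 6.23, in intron 18. Pax3, a marker of muscle progenitors, had 3.73 kb (7.01 kb in replicate 2), and Myod1, which commits cells to muscle, had 0.561 kb, with none in replicate 1 and 2.37 kb in replicate 2. Lmbr1, whose introns hold a distant limb enhancer of Shh, had no replicated peak within 50 kb of its TSS and 1 in its gene body, in intron 5, from 29313978 to 29314162 on chromosome 5 with a fold of 3.80. Replicate 2 had an overlapping peak there with a fold of 4.18, whereas the only peak of replicate 1 in the gene lay in the same intron from 29315393 to 29315588 with a fold of 4.33 and did not overlap it. In all, replicate 2 had 5 peaks in the gene, in introns 1, 5 and 10. The position of the enhancer was not compared with these peaks.

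The sequence under the summits was richer in GC and CpG than random DNA, and some motifs, a pair for HOX proteins among them, had a higher ratio of summits to flanks than permutations of their letters. Within 250 bp of the summit the GC content was 50.1% against 42.1% at random, and the ratio of observed to expected CpG was 0.288 against 0.194. Of 20 consensus motifs fixed before the data were examined, counted against flanks 10 kb away, 3 stood above every permutation of their own letters. The HOX homeodomain motif TAATTA had a ratio of 0.917 against a median of 0.619 over 13 permutations (log2 0.57), so it was rarer at summits than in flanks, but less so than its permutations were. The PBX-HOX motif TGATTTAT had a ratio of 1.02 against 0.620 over 20 permutations (log2 0.72), and the TEAD motif GGAATG had 1.14 against 1.02 (log2 0.17). All 3 also stood above every permutation in each replicate and within 100 bp of the summit. At that width the ratio of the PBX-HOX motif fell under 1, to 0.803, and that of TAATTA was 0.720, so both were then rarer at summits than in flanks. Other homeodomain motifs did not stand out, as 3 of 20 permutations were as high as the HOX13 motif CAATAAAA (log2 0.26) and 18 of 20 as high as the PITX motif TAATCC (log2 -0.29). The E-box CAGCTG of MYOD was passed by 1 of 20 permutations, and by 0 both in replicate 2 alone and within 100 bp of the summit (log2 0.40). The CTCF motif had a log2 ratio of -0.50, which was 0.01 in replicate 2 alone and -1.33 within 100 bp, where all 20 permutations were as high, and the HNF1 motif was too rare to count. With at most 20 permutations for each of 20 motifs, about 1 motif stands above all of its permutations by chance, and on simulated data 1 of 17 motifs that had not been planted stood above all of its permutations.

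Chromosomes differed in how much of their length the mark covered. Autosomes were covered over a mean of 1.47 ± 0.391% (SD, n = 19 chromosomes), from 0.960% on chromosome 3 to 2.59% on chromosome 11. The X chromosome, with 256 peaks, was covered over 0.0560%. The share of the joint length of all autosomes was 26.1 times that of the X, and this ratio was 22.3 in replicate 1 and 15.2 in replicate 2. The Y chromosome had 0 peaks in every list. The ratio to the X moved by over 1.5 times without replicate 1, and no test was made.

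**Figure D5:**
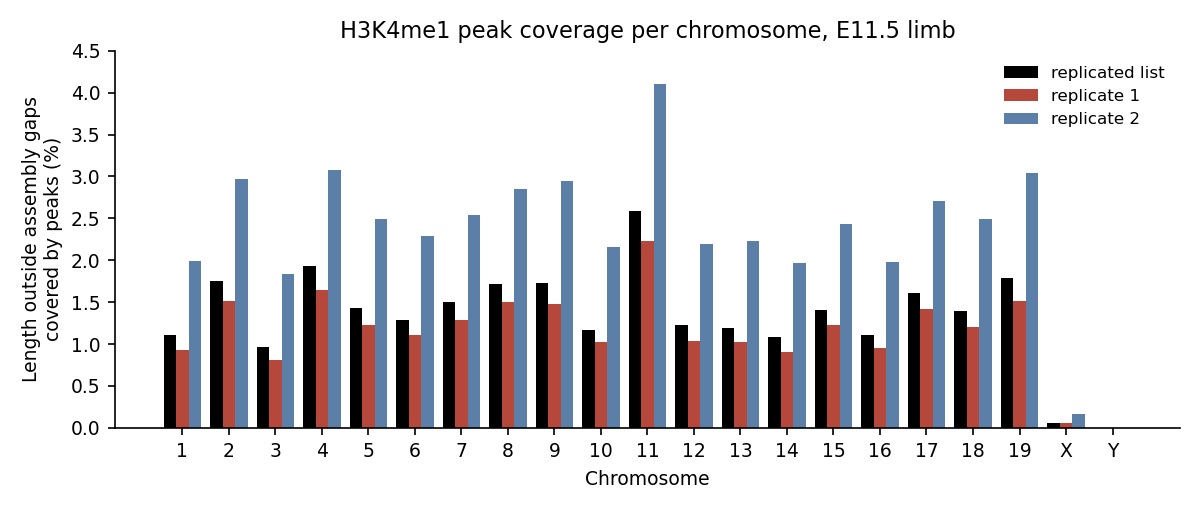
Percent of each chromosome outside assembly gaps covered by H3K4me1 peaks, for the replicated list and each replicate. In the replicated list autosomes lie between 0.960% and 2.59% and the X chromosome at 0.0560%.

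The replicates shared most of the shorter list. Of the peaks of replicate 1, 76.8% overlapped a peak of replicate 2 by at least 1 bp (Wilson 95% interval 76.5% to 77.1%), against 4.54% when the same peaks were placed at random. Of the peaks of replicate 2, 39.1% overlapped one of replicate 1 (38.8% to 39.3%). These intervals treat neighbouring peaks as independent and do not measure the spread between replicates. With lists of the same length, taken by p, the share was 61.9%, and between equal numbers of the strongest peaks it was 48.9% for 10000 and 35.5% for 1000. Set against any peak of the other replicate, peaks with a -log10 q of at least 3 overlapped more often than all peaks did, at 89.8% for replicate 1 and 57.3% for replicate 2. Heights at 63380 overlapping pairs had a Spearman correlation of 0.295 and a Pearson correlation of 0.363, across peaks, which are not independent replicates. Replicate 2 had 1.81 times as many peaks as replicate 1, and 1.32 times as many with a fold of at least 4. Peaks with a -log10 q of at least 3 numbered 30549 in replicate 1 and 68735 in replicate 2, so by that measure the excess was not smaller. Under the Poisson model, however, the same pileup over the same background scored a lower -log10 p in replicate 1. These counts were thus taken at unlike limits, whereas the fold does not depend on the scoring. Every replicated peak was identical to a pooled peak. Of these, 96.1% overlapped a peak of replicate 2 and 78.4% a peak of replicate 1 by at least 1 bp. At least 50% of the length was covered by a single peak of replicate 1 for 66.3%, of replicate 2 for 92.4%, and of both for 59.3%. The coverage of several peaks was not added up. These shares are of what each list reports, and a site missing from a list was not shown to lack the mark.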

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

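Of the tests in this part, those of the read totals and of the scaling of the pooled reads were chosen only after the result was seen. Peaks outside the replicated list were not used in the main comparisons, and many were strong by the authors' own values. Replicate 1 had 2207 peaks with a -log10 q of at least 3 outside the replicated list, and replicate 2 had 19782. Under the Poisson model the scoring of replicate 1 was the stricter, so these counts were taken at unlike limits. In all, 23.0% of the peaks of replicate 1 and 53.5% of those of replicate 2 lay outside it, with median folds of 3.21 and 3.08 and highest folds of 5.62 and 6.44. A control sample was not analysed here, so the level such peaks reach without the mark is not known.

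The first pattern weighed was that replicate 2 lists 1.81 times as many peaks as replicate 1. Deeper sequencing was argued against, since the control scaling in the deposited values put the reads of replicate 2 at 0.966 times those of replicate 1. Chance peaks spread evenly over each chromosome were argued against as the whole cause. Of the peaks in replicate 2 only, 57.4% lay within 5 kb of a replicated peak against 15.9% of random places, a ratio of 3.6. Chance peaks that favour the same regions as replicated peaks were not tested. The ratio was 3.67 for peaks in replicate 1 only, so it does not tell why the list of replicate 2 is longer. Scoring in replicate 1, stricter by 1 read, stays open, since giving summits of replicate 2 that rule left it 1.79 times as long but moved only 1.49% of summits past the lowest p, and the narrowing of weak peaks was not modelled. A higher enrichment in replicate 2 also stays open as a possible explanation, as the median ratio of folds at shared sites was 1.048, just short of the level set for it, with 58.4% of sites higher in replicate 2, while over all overlapping pairs it was 1.098 with the highest overlapping peak and 1.086 with the longest overlap; no biological explanation was tested, since the replicates belong to 1 group.

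The second pattern was that the pooled list, made from more reads, has 94426 peaks where replicate 2 alone has 149679. The deposited pooled values were met by pileups in steps of 0.509 reads, which is consistent with pooled reads scaled down to the depth of the control, so that pooling would add no height. Among peaks of replicate 2 with folds of 3 to 4, 96.6% of those with a peak in replicate 1 were kept in the pooled list and 30.9% of those without, a difference of 65.7 percentage points. Peaks without a replicate 1 peak have low signal there by selection, so a lower share kept was fixed in advance for true sites and chance peaks alike. The difference shows that such peaks often drop out of the pooled list, but not whether they are sites that only replicate 2 has. The shares of the shortening due to this loss and to the scaling were not separated. No biological explanation was tested.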

How the results depend on the processing

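The Fisher tests on spaced members and spaced other genes were chosen after seeing the data. So were the alternatives for chromosome coverage, for sequence content except the width of 100 bp, and for the TSS profile. Of list and setting pairs for gene list coverage, 250 of 264 kept their direction and side of the threshold, 8 lost the call and 6 gained one. For the top 10% 151 of 154 pairs did, 2 lost it and 1 gained it, and for the longest clusters 171 of 176 did, 4 lost it and 1 gained it. None of these reversed. Between 6 and 11 lists stood above random over the alternatives, against 8, and 0 stood below with -log10 q of at least 3, against 1. For promoters, introns and intergenic DNA the direction held in all 8 alternatives, and in exons the log2 ratio reversed to -0.0076 with promoters of 2.5 kb, which take over exon sequence near TSS. The overlap of replicate 1 with replicate 2 moved to 64.3% at 50% of the peak, 35.7% at 50% of both peaks, 64.0% by summits, 74.9% with -log10 q of at least 3 and 58.5% with folds of at least 4. In the same order the overlap of replicate 2 moved to 22.9%, 19.7%, 26.7%, 31.2% and 39.8%. Ranked by fold, the share at matched length was 60.1%, and the Pearson correlation on the log2 scale was 0.327. The share of replicated peaks overlapping both replicates was 74.7% at 1 bp and 73.0% at 50% of either peak, and that of pooled peaks was 59.1% and 56.6%. Leaving out a replicate, the ratio of autosomes to the X ranged from 15.2 to 22.3, the coverage of HoxC from 25.3% to 34.3% and that of HoxB from 8.62% to 19.6%, the GC excess from 6.72 to 8.11 percentage points and the CpG excess from 0.0842 to 0.0929. Within 100 bp of the summit these excesses were 9.84 and 0.0826. With -log10 q of at least 3 the coverage was 27.4% for HoxA, 3.69% for HoxB, 12.3% for HoxC and 17.9% for HoxD, and with the stronger peaks by p that of HoxC was 17.9%, each with fewer peaks by construction. For the other changes the cause was not tested. Depth limits the height of single peaks. Over the background of the whole genome, the counting error of 14 reads allows folds of 2.32 to 6.56 in replicate 1. That of 13 reads allows 2.22 to 6.5 in replicate 2. These reads are the median pileups, and only 35.7% of peaks in replicate 1 and 35.2% in replicate 2 lay at that background.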

Other observations

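Of the tests in this part, that of gene number on the X, that of dose and gene number together, that of the DNA of both sexes, and the stricter limits of p were chosen only after the result was seen. On the X chromosome the highest replicated peak lay 8.17 kb from the TSS of Bcor, a transcriptional corepressor (12151864 to 12152373, fold 5.23), and another in intron 1 of Bcor had a fold of 4.38. A peak with a fold of 4.81 lay 19.6 kb from Pja1, a ubiquitin ligase gene, and one with a fold of 4.41 in intron 2 of Gpc3, a glypican gene of growth control, without a peak in replicate 1. These genes were named after their values were seen.

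Peaks found in 1 replicate only lay near shared sites in both replicates. Within 5 kb of a replicated peak lay 59.5% of 16512 such peaks of replicate 1, against 16.2% of random places, and 57.4% of 77344 of replicate 2, against 15.9%. Promoters held 17.4% and 15.4% of their summits.

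The third pattern weighed was the low number of peaks on the X chromosome. A smaller number of genes was argued against as the whole cause, as the X had 0.0769 times as many replicated peaks per protein-coding gene as the autosomes. Signal in proportion to the DNA of an even pool of both sexes, 0.75 of the pileup, was argued against too, as it predicted 16.1 and 10.2 times the observed X peak density in replicates 1 and 2, and at least 4.8 times with peaks counted only above the lowest 5% or above the median of p. Halved signal, as with 1 active copy of the X in either sex, stays open: it predicted 4.28 and 3.75 times the observed density, or 2.85 and 2.5 times when scaled to gene number too, but that count takes in summits down to the lowest p of each list without the width a peak needs, and above the lowest 5% of p it predicted 1.14 and 1.29 times, above the median 0.151 and 0.505 times. At the background of the whole genome lay 71.7% of X peaks against 35.5% of autosomal peaks in replicate 1, and 75.4% against 35.0% in replicate 2; how X reads were mapped and filtered, and any biological explanation, were not tested.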
